A study of Mus musculus with 12 samples.

How the data were processed

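Poly(A) RNA of the hippocampus was measured in 12 libraries from male mice, 4 each for the groups Control, Model and Treatment, which were taken from the sample labels. Per the labels all libraries are of 1 batch, and the names of Treatment replicates 2 and 3 carry numbers (1631 and 1636) apart from those of the other 10. Per the submitters' processing notes Trim Galore 0.6.7, cutadapt 3.4, FastQC 0.12.1, STAR 2.7.10a and Salmon 1.10.1 were used with the builds GRCm39 and mm39. The notes give no roles, annotation release or filters. The deposited table holds an estimated count per gene and library, not scaled by the authors: 28.8% of the nonzero values are not whole numbers within a tolerance of 1e-06. It also holds deposited FPKM values, which the authors scaled by gene length and by the total of each library. Of its 78298 genes 21883 have no gene symbol.

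Estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr left 18600 genes, library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries. Model was compared with Control, Treatment with Model, and Treatment with Control. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, over all genes of a comparison. Log2 fold changes are given with SE, from the fold change and its test statistic. CPM values use the TMM-scaled library sizes. Scores and correlations use log2 CPM with a prior count of 2.

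Before the data were examined, 44 gene lists were written for processes studied in stress and depression, for cell types, for tissues that adjoin the hippocampus and for its subfields. The comparisons, the rule for named genes and most of the alternatives were written at the same time. Lists were tested in camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The tests were repeated with the correlation estimated for each list and in fry. For 14 lists of other tissues, other cell types and subfields, group means of the score were also compared by an exact permutation test over the 70 arrangements of 4 and 4 libraries. Named genes are of 4 kinds. The 10 largest changes in each direction were taken among genes that passed, had a mean of at least 1 CPM and did not overlap between the groups, skipping clone names and unnamed identifiers. From each list that passed, the 4 members of smallest p were taken, and from other lists up to 2 members that passed. The last kind is a fixed set of 15 genes of stress and depression research. A gene that the rule selects is not reported here. Names outside this rule are said to be chosen after their values were seen.

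Because Model enters both of the first comparisons, their covariance was compared with that in 30 simulated data sets without an effect. It was also computed with the Model libraries split into pairs in all 6 ways, each comparison using another pair. The alternatives tried were RLE scaling, DESeq2 1.42.0, limma-voom, no filter and a filter of at least 1 CPM in 8 libraries, and fits of only the 8 libraries compared. Others were a replicate block, leaving out each library and leaving out Treatment replicates 2 and 3 together, the choroid plexus score as a covariate, a fold threshold, and the FPKM values (at least 0.5 in 4 libraries) with pseudocounts of 0.1 and 1 in limma. Chosen after seeing the data were offsets for each library's loess trend on GC content and transcript length, and the neocortical score as a covariate. GC content and length came from the longest transcript of each gene in the GENCODE vM21 annotation of the earlier GRCm38 build, matched by gene identifier. Other tools were data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.

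Library totals of 17083260 to 27479083 counts and the biological coefficient of variation of 10.7% set the precision. The procedure was tested on simulated data with known changes. Of genes changed by 0.4, 0.8 and 1.5 log2 units it called 47.8%, 77.6% and 92.4% in the Model and Control libraries, with 9 false calls among 18110 unchanged genes, and 41.8%, 73.1% and 92.4% in the Treatment and Model libraries, with 8 false calls. A list shifted by 0.3 was called and 0 other lists were. Genes were simulated independently of each other, whereas the heat shock list had an estimated correlation of 0.49 in the data. These simulations thus do not show how many false calls of lists or genes arise where genes vary together. A covariance of -0.0110 put in was recovered as -0.0109. Reads were not realigned, since only the processed table was used, so splicing and sequence variants were left out.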

Results

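Poly(A) RNA from the hippocampus of male C57BL/6 mice was sequenced in 12 libraries, 4 in each of 3 groups. Control mice were not stressed and received saline. Model mice went through chronic unpredictable mild stress, a schedule of changing mild stressors that serves as a model of depression, for 28 days. They too received saline. Treatment mice went through the same schedule and also received poricoic acid A, a triterpenoid of the fungus Poria cocos, by gavage at 20 mg/kg daily for 14 days. The estimated counts of a library added up to between 17083260 (Control replicate 3) and 27479083 (Control replicate 2), and those of the Model and Treatment libraries to between 18169849 and 23665426. Of the 78298 genes listed, 18600 passed the count filter and were tested in edgeR. At this depth and spread (biological coefficient of variation 10.7%) most changes found were well below 2-fold. Gene changes are given as log2 fold changes ± SE from edgeR with n = 4 libraries per group, and expression levels as library-scaled counts (CPM) ± SD. The labels state 4 per group without saying that every library is a separate animal, so the p-values measure the spread between these samples.

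The comparison of Model with Control addressed what 28 days of stress change in the hippocampus. Chaperone genes of the endoplasmic reticulum and the cytosol rose. As lists, immediate early genes were also higher and cholesterol, myelin and choroid plexus genes lower, with 2 or 3 members of each past the threshold singly. With a correlation between genes estimated from the data no list passed. All 30 measured members of the fixed list of heat shock and unfolded protein response genes had a positive fold change, with a median of 0.37. Hspa5, the main chaperone of the endoplasmic reticulum, went from 192 ± 14.9 CPM in Control to 335 ± 79.8 CPM in Model (SD, n = 4 each). Of the 18600 genes, 147 passed an adjusted p of 0.05, 63 higher and 84 lower in Model.

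Of the heat shock and unfolded protein response list, 14 rose, 0 fell and 16 did not pass; 23 rose and 0 fell when adjusted over the list alone. Its set test gave adjusted p = 4.95e-25, and adjusted p = 0.267 with an estimated correlation. Folding and quality-control genes of the endoplasmic reticulum were among the members that rose. Sdf2l1, a partner of its DnaJ proteins, changed by 1.11 ± 0.20, adjusted p = 0.0212, Hspa5 by 0.81 ± 0.15, adjusted p = 0.0219, and Manf, a secreted stress-response factor, by 0.67 ± 0.12, adjusted p = 0.0212. Creld2, an isomerase of the same compartment, changed by 0.67 ± 0.13 (adjusted p = 0.0308) and Hsp90b1, its Hsp90, by 0.46 ± 0.07 (adjusted p = 0.0148). Derl3, which is outside the list and takes part in the removal of misfolded proteins, rose by 1.53 ± 0.32 (adjusted p = 0.0384). Of the cytosolic chaperones, Hspa1b, an inducible Hsp70, went from 12.1 ± 1.44 to 25.2 ± 8.33 CPM (1.07 ± 0.22, adjusted p = 0.0424), and Hsph1, a nucleotide exchange factor of Hsp70, rose by 0.49 ± 0.08 (adjusted p = 0.0155). The mean score of this list, in log2 units around the mean of all libraries, lay between -0.24 and -0.21 in the 4 Control libraries. In Model it was 0.10, 0.09 and 0.14 in replicates 1 to 3 and 0.43 in replicate 4.

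Among 24 immediate early genes, 3 rose, 0 fell and 21 did not pass (6 rose and 0 fell when adjusted over the list alone). These were Fosb, a transcription factor of the AP-1 family that accumulates with repeated activity (0.87 ± 0.13, adjusted p = 0.0111), Inhba, a subunit of activin (0.83 ± 0.17, adjusted p = 0.0357), and Egr3 (0.50 ± 0.09, adjusted p = 0.0212). The list had 14 positive and 10 negative fold changes, with a median of 0.10. It passed with adjusted p = 0.00856, and adjusted p = 0.321 with an estimated correlation, but not without Model replicate 4 (adjusted p = 0.0937). Fos itself differed by 0.28 ± 0.28, adjusted p = 0.691. Of 36 glutamatergic synapse genes 32 had positive fold changes, with a median of 0.07 (adjusted p = 6.12e-04, and adjusted p = 0.302 with an estimated correlation). The 1 that rose was Homer1, a postsynaptic scaffold with an activity-induced short form (0.69 ± 0.14, adjusted p = 0.0316). Of 31 GABAergic genes 25 were positive (median 0.09, adjusted p = 1.41e-04, and adjusted p = 0.247 with an estimated correlation), and 0 rose (3 adjusted over the list alone). Gad1, which makes GABA, differed by 0.23 ± 0.06, adjusted p = 0.104. Of 28 genes of presynaptic vesicle release 1 rose, Syt4 (0.32 ± 0.06, adjusted p = 0.0295). The median of that list was 0.05 (adjusted p = 0.0107, and adjusted p = 0.456 with an estimated correlation; without Control replicate 3 adjusted p = 0.0804). Monoamine receptors and metabolism had a median of 0.16 (adjusted p = 0.00856, and adjusted p = 0.302 with an estimated correlation). Neurotrophin signalling had one of 0.11 (adjusted p = 0.00856, and adjusted p = 0.302 with an estimated correlation). The single member of either list that rose was Htr1a, the serotonin 1A receptor (0.38 ± 0.06, adjusted p = 0.0183). Cbfa2t3, a transcriptional corepressor, had the smallest adjusted p of this comparison (0.72 ± 0.06, adjusted p = 4.00e-05). Fosb, Cbfa2t3 and Lncppara passed whichever single library was left out.

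Choroid plexus genes were the most strongly lower group: all 23 measured members had negative fold changes, with a median of -1.24. Over all genes 2 of them fell, Abca4 (-1.35 ± 0.29, adjusted p = 0.0454) and Sostdc1 (-1.21 ± 0.26, adjusted p = 0.0469). The other 21 did not pass, although 23 fell when adjusted over the list alone. The list passed with adjusted p = 5.18e-18, and adjusted p = 0.321 with an estimated correlation. Ttr, which encodes transthyretin and is made in quantity by the choroid plexus, stood at 1513, 1853 and 2015 CPM in Control replicates 1 to 3 but 600 CPM in replicate 4. In Model it stood at 497 to 725 CPM (-1.38 ± 0.36, adjusted p = 0.0820). The choroid plexus score likewise was 0.80, 1.11 and 1.14 in Control replicates 1 to 3 and -0.26 in replicate 4, and between -0.53 and -0.12 in Model. Its difference had p = 0.0571 in an exact two-sided permutation test, whose smallest possible p is 0.0286 (adjusted p = 0.240 over 14 lists). Ependymal markers had a median of -0.36 (adjusted p = 0.00856, and adjusted p = 0.562 with an estimated correlation; without Model replicate 4 adjusted p = 0.0827). Red blood cell genes had one of -0.53 (adjusted p = 2.15e-04, and adjusted p = 0.321 with an estimated correlation) and leptomeningeal and fibroblast genes one of -0.14 (adjusted p = 0.0108, and adjusted p = 0.498 with an estimated correlation; without Model replicate 2 adjusted p = 0.0590). Igf2, a growth factor, fell from 131 ± 35.5 to 65.4 ± 5.80 CPM (adjusted p = 0.0212). Igfbp2, which binds it (-1.07 ± 0.23, adjusted p = 0.0471), and Hbb-bt, a beta globin (-0.84 ± 0.17, adjusted p = 0.0316), fell. In the list of extracellular matrix genes, 0 rose, 2 fell and 28 did not pass (0 rose and 11 fell when adjusted over the list alone). Its median was -0.20 (adjusted p = 3.73e-05, and adjusted p = 0.302 with an estimated correlation). Nid2, a basement membrane protein (-0.88 ± 0.19, adjusted p = 0.0461), and Col9a3 (-0.98 ± 0.22, adjusted p = 0.0472) fell. So did Sulf1, an extracellular sulfatase outside the lists (-1.30 ± 0.26, adjusted p = 0.0316), which like the choroid plexus score was high in Control replicates 1 to 3 (35.1, 51.9 and 44.4 CPM) and not in replicate 4 (17.7 CPM). Sulf1, Igf2, Nid2 and Col9a3 were also among the 80 genes of a split of Control and Treatment libraries that follows choroid plexus RNA. That split uses the same Control replicates 1 to 3, so it does not settle the source of these genes.

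Cytosolic ribosomal protein genes were lower by little but in unison: all 79 had negative fold changes and 0 passed singly (median -0.12, adjusted p = 4.59e-09, and adjusted p = 0.536 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, mt-Nd5, a subunit of complex I, fell (-0.30 ± 0.05, adjusted p = 0.0183). The median of these mRNAs was -0.16 (adjusted p = 0.00418, and adjusted p = 0.488 with an estimated correlation). Of 25 cholesterol genes 0 rose, 2 fell and 23 did not pass (0 rose and 6 fell when adjusted over the list alone). Their median was -0.09 (adjusted p = 1.69e-04, and adjusted p = 0.376 with an estimated correlation). Among those that fell was Lss, which forms lanosterol (-0.40 ± 0.07, adjusted p = 0.0212). Of 24 oligodendrocyte and myelin genes 0 rose, 2 fell and 22 did not pass (0 rose and 4 fell when adjusted over the list alone). The member Enpp2 (-1.10 ± 0.26, adjusted p = 0.0594) was high where the choroid plexus score was. It stood at 1340, 1513 and 1675 CPM in Control replicates 1 to 3, 636 CPM in replicate 4 and 529 to 712 CPM in Model. Enpp2 is also among the 80 genes of the split that follows choroid plexus RNA. The myelin median was -0.13 (adjusted p = 3.73e-05, and adjusted p = 0.498 with an estimated correlation). Aspa, which breaks down N-acetylaspartate, changed by -0.48 ± 0.08 (adjusted p = 0.0169) and Opalin, a myelin membrane protein, by -0.42 ± 0.08 (adjusted p = 0.0212), whereas Mbp differed by -0.16 ± 0.07, adjusted p = 0.311. Homeostatic microglia genes had a median of -0.13 (adjusted p = 2.15e-04, and adjusted p = 0.376 with an estimated correlation) and antigen presentation genes one of -0.21 (adjusted p = 0.00458, and adjusted p = 0.321 with an estimated correlation). No member passed in either list. Siglech, a microglial receptor, differed by -0.31 ± 0.08, adjusted p = 0.0820. The 20 circadian clock genes did not pass as a list (adjusted p = 0.959). Of them 2 fell, the transcription factor Dbp (-0.54 ± 0.12, adjusted p = 0.0473) and the clock repressor Ciart (-0.98 ± 0.22, adjusted p = 0.0475). Among the largest decreases outside these lists were those of Myo5c, a myosin (-1.44 ± 0.23, adjusted p = 0.0155), and Lncppara, a noncoding RNA (-1.41 ± 0.17, adjusted p = 0.00321). Others were those of Pla2g4e, a phospholipase (-1.27 ± 0.26, adjusted p = 0.0337), and Atcayos (-1.09 ± 0.17, adjusted p = 0.0148). Atcayos and Lncppara are noncoding transcripts named after a gene beside them, and the labels do not say whether the libraries kept the strand.

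Markers of hippocampal fields were on balance higher in Model. All 17 measured CA1 markers were positive with a median of 0.20 (adjusted p = 1.69e-04, and adjusted p = 0.321 with an estimated correlation), and Etv1 among them differed by 0.31 ± 0.09, adjusted p = 0.104. The CA2 and CA3 list had a median of 0.15 (adjusted p = 0.00856, and adjusted p = 0.456 with an estimated correlation; without Model replicate 3 adjusted p = 0.0591). The dentate gyrus list had one of 0.08 (adjusted p = 0.0233, and adjusted p = 0.498 with an estimated correlation). Without Model replicate 3 its adjusted p was 0.316, and without Control replicate 2 it was 0.196. Trpc6, a cation channel of granule cells, rose (0.50 ± 0.10, adjusted p = 0.0295), as did Neurod2, a neuronal transcription factor (0.34 ± 0.07, adjusted p = 0.0499). The call of the thalamus and habenula list (median -0.46, adjusted p = 0.0218, and adjusted p = 0.663 with an estimated correlation) rested on Control replicate 1, whose score was 1.37: without it the test turned the other way with adjusted p = 0.792. The call ended too without Model replicates 1, 3 or 4 (adjusted p = 0.0842, 0.0743 and 0.0684). Lists of pericytes (-0.12, adjusted p = 0.0418, and adjusted p = 0.488 with an estimated correlation), disease-associated microglia (-0.12, adjusted p = 0.0452, and adjusted p = 0.536 with an estimated correlation) and reactive astrocytes (0.13, adjusted p = 0.0420, and adjusted p = 0.457 with an estimated correlation) passed narrowly. The pericyte call ended without Control 2 (0.0837), 4 (0.231), Model 2 (0.0772), 3 (0.0658) or 4 (0.05002). The call of disease-associated microglia ended without Control 2 (0.0837), 3 (0.135), 4 (0.0508), Model 1 (0.0888), 2 (0.110), 3 (0.0587), Treatment 2 (0.0522) or 4 (0.0527), and that of reactive astrocytes without Control 1 (0.0827), 2 (0.0575), 4 (0.0593), Model 2 (0.0593), 3 (0.0591), 4 (0.146) or Treatment 3 (0.0508).

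In all, 25 of 44 lists passed (11 up and 14 down). The number was 0 with camera's estimated correlation (6 at an unadjusted p under 0.05, smallest adjusted p = 0.247), and 2 in fry, a test of the list against no change: heat shock genes and GABAergic genes, each with adjusted p = 0.0378. At an unadjusted p under 0.05 there were 2896 genes, and 21 of the genes that passed changed at least 2-fold (4 higher, 17 lower). In 2123 genes, 11.4%, the 4 Model and 4 Control libraries did not overlap, where chance gives 2.86%. The count of 147 genes became 8 and 12 without Control replicates 1 and 2, 14, 13 and 12 without Model replicates 2, 3 and 4, and 274 and 275 without Treatment replicates 1 and 3. It was 2 with the choroid plexus score as a covariate and 692 in DESeq2 (428 higher, 264 lower). It was 88 in limma-voom, 783 without a filter, 438 with only the 8 libraries compared, 228 with a replicate block, 306 without Treatment replicates 2 and 3 together and 5 with FPKM values, where 2 of the 36 named genes that passed still did. With GC and length trends removed it was 472 (254 higher, 218 lower), and the lists of the dentate gyrus, disease-associated microglia and reactive astrocytes did not pass (adjusted p = 0.1196, 0.0980 and 0.0669).

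**Figure D1:**
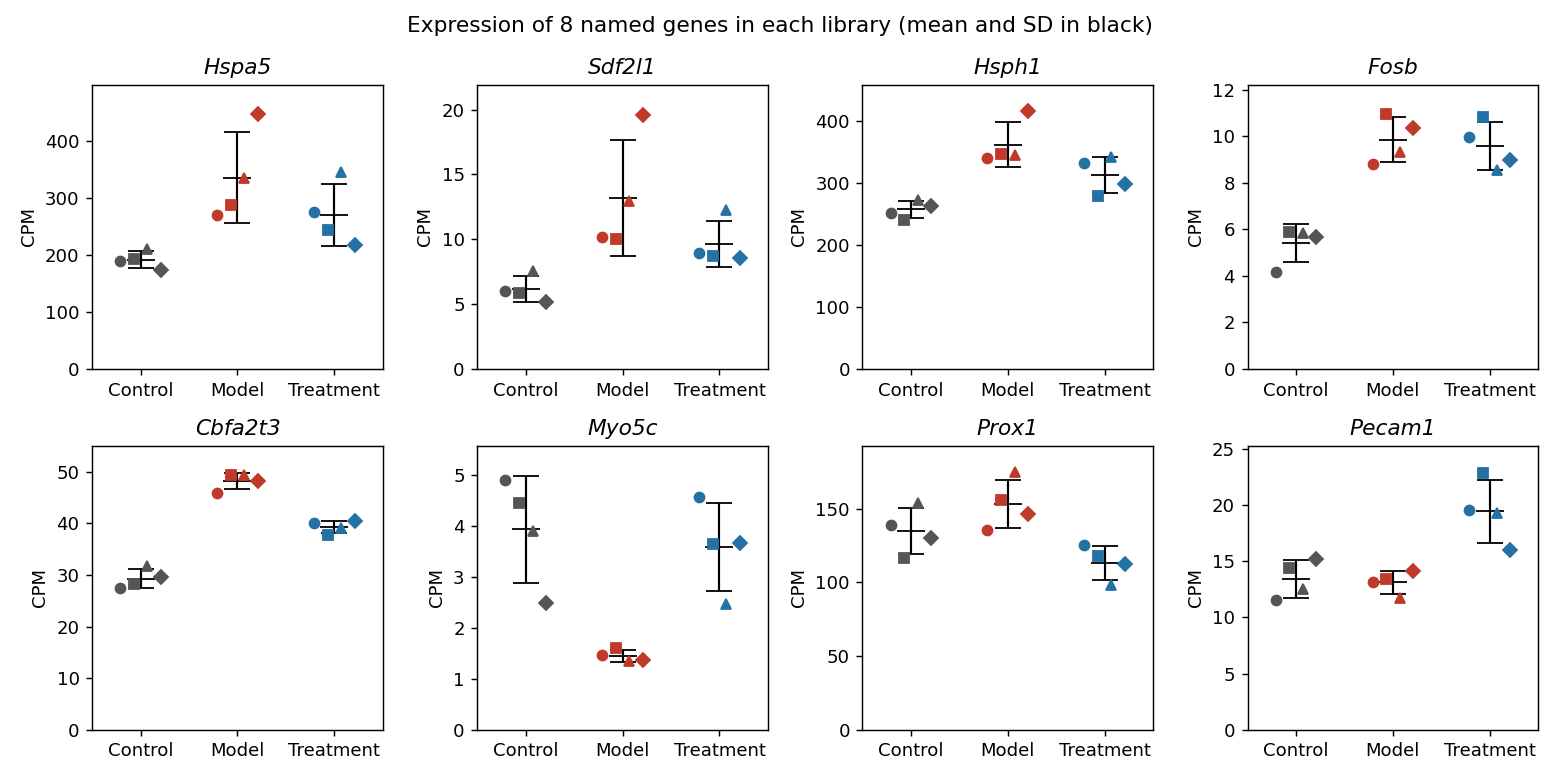
Expression in CPM (y axis) of 8 named genes in each of the 12 libraries by group (x axis), with replicates 1 to 4 as circles, squares, triangles and diamonds and the mean ± SD in black. Hspa5 averaged 192 CPM in Control, 335 in Model and 270 in Treatment, and Myo5c 3.94, 1.45 and 3.59 CPM.

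Treatment was set against Model to ask what poricoic acid A changes in stressed mice. As lists, granule cell genes of the dentate gyrus were lower after the compound, while endothelial, pericyte, antigen presentation and neocortical genes were higher, with 1 to 5 members of each past the threshold singly. Heat shock and unfolded protein response genes were lower as a list. With a correlation between genes estimated from the data no list passed. Of the measured dentate gyrus markers 19 of 20 were negative, with a median of -0.27, and of the endothelial markers 20 of 22 were positive, with a median of 0.24. In edgeR 350 genes passed an adjusted p of 0.05, 219 higher and 131 lower in Treatment.

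In the dentate gyrus list 0 rose, 5 fell and 15 did not pass (1 rose and 11 fell when adjusted over the list alone). The list passed with adjusted p = 1.95e-08, and adjusted p = 0.242 with an estimated correlation. Prox1, the transcription factor that sets granule cell identity, went from 153 ± 16.6 to 113 ± 11.5 CPM (-0.43 ± 0.10, adjusted p = 0.0331). Trpc6 (-0.58 ± 0.10, adjusted p = 0.0174) and the guidance molecule Sema5a (-0.49 ± 0.10, adjusted p = 0.0259) fell. The synaptic organiser C1ql3 (-0.30 ± 0.06, adjusted p = 0.0305) and the calcium-binding protein Calb1 (-0.33 ± 0.07, adjusted p = 0.0341) fell as well. The score of this list lay between -0.17 and -0.06 in Treatment and between 0.07 and 0.24 in Model. The exact permutation test gave p = 0.0286, the smallest possible (adjusted p = 0.1). Of 22 CA2 and CA3 markers 19 were negative with a median of -0.18 (adjusted p = 0.00185, and adjusted p = 0.586 with an estimated correlation). In that list Cpne4 fell (-0.33 ± 0.07, adjusted p = 0.0363) and Coch rose (0.86 ± 0.19, adjusted p = 0.0342). The CA1 list did not pass (median -0.18, adjusted p = 0.0543). Gria1, an AMPA receptor subunit, fell (-0.33 ± 0.08, adjusted p = 0.0446).

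Neocortical markers moved the other way over the same libraries. Of 20 measured, 18 were positive with a median of 0.49 (adjusted p = 1.11e-05, and adjusted p = 0.308 with an estimated correlation). In the list 4 rose, 0 fell and 16 did not pass (9 rose and 1 fell when adjusted over the list alone). Cux2, of upper cortical layers (0.81 ± 0.18, adjusted p = 0.0366), Lamp5 (0.69 ± 0.16, adjusted p = 0.0430), Whrn (0.54 ± 0.11, adjusted p = 0.0283) and Rspo1, a Wnt agonist (1.85 ± 0.35, adjusted p = 0.0217), rose. The neocortical score was 0.41 and 0.50 in Treatment replicates 1 and 4, 0.18 and 0.05 in replicates 2 and 3, and between -0.41 and -0.05 in Model (exact permutation p = 0.0286, adjusted p = 0.1). Of this list 18 genes reached a mean of 1 CPM in every group. The largest increases included that of Igfn1, an immunoglobulin-like muscle protein (2.19 ± 0.323 to 12.6 ± 6.56 CPM, 2.52 ± 0.43, adjusted p = 0.0175). They also included those of Col24a1, a fibrillar collagen (1.76 ± 0.42, adjusted p = 0.0438), Dkkl1 (1.74 ± 0.36, adjusted p = 0.0277) and Kcnh4, a potassium channel (1.58 ± 0.29, adjusted p = 0.0199). Among the largest decreases was that of Cbln3, a cerebellin of cerebellar granule cells (-4.07 ± 0.92, adjusted p = 0.0363). It stood at 27.3, 7.22, 0.792 and 3.52 CPM in the Model libraries and at most 0.709 CPM in Treatment. With single libraries left out its change ranged from -4.46 to -2.73, and leaving out any 1 of 7 libraries ended its call. The number of such libraries was 11 for Lamp5, 9 for Col24a1 and 7 for Cux2. It was 4 for Whrn, 3 for Dkkl1 and 2 each for Rspo1, Igfn1 and Kcnh4.

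Endothelial genes rose as a list (adjusted p = 7.77e-07, and adjusted p = 0.242 with an estimated correlation), where 2 rose, 0 fell and 20 did not pass (11 rose and 0 fell when adjusted over the list alone). Pecam1, an adhesion protein of endothelial junctions, went from 13.1 ± 1.01 to 19.4 ± 2.79 CPM (0.57 ± 0.11, adjusted p = 0.0256), and Slco1a4, a transporter of the blood-brain barrier, rose by 0.39 ± 0.08 (adjusted p = 0.0246). Pericyte and smooth muscle genes had a median of 0.34 (adjusted p = 6.81e-06, and adjusted p = 0.242 with an estimated correlation), and Myl9, a smooth muscle myosin light chain, rose (0.54 ± 0.13, adjusted p = 0.0458). Vegfa, an endothelial growth factor, rose by 0.35 ± 0.06 (adjusted p = 0.0179). The endothelial and pericyte scores each had an exact permutation p of 0.0286 (adjusted p = 0.1). Extracellular matrix genes had a median of 0.15 (adjusted p = 0.0252, and adjusted p = 0.586 with an estimated correlation). Col5a1, a fibrillar collagen (15.6 ± 3.97 to 33.6 ± 9.90 CPM, adjusted p = 0.0199), and Col4a2, a basement membrane collagen (0.36 ± 0.08, adjusted p = 0.0357), rose. That list did not pass without Treatment replicate 2 (adjusted p = 0.189), Treatment replicate 3 (0.0551) or Model replicate 4 (0.113). Antigen presentation genes rose as a list (median 0.34, adjusted p = 5.19e-05, and adjusted p = 0.242 with an estimated correlation) with 19 of 20 positive. H2-T23, a class I molecule, rose (0.71 ± 0.15, adjusted p = 0.0301), and H2-D1 differed by 0.31 ± 0.08, adjusted p = 0.0624. Interferon-stimulated genes had a median of 0.26 (adjusted p = 0.00164, and adjusted p = 0.586 with an estimated correlation), with no member past the threshold. Their score was 0.45 in Treatment replicate 3, without which the list had adjusted p = 0.0834. Homeostatic microglia genes had a median of 0.13 (adjusted p = 7.17e-04, and adjusted p = 0.586 with an estimated correlation), where C1qb, a complement component, differed by 0.33 ± 0.09, adjusted p = 0.0808. Rela, a subunit of NF-kB, rose (0.40 ± 0.08, adjusted p = 0.0305).

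Of the heat shock and unfolded protein response genes 25 of 30 were negative (median -0.15, adjusted p = 3.30e-05, and adjusted p = 0.586 with an estimated correlation). Of these 0 rose, 2 fell and 28 did not pass (0 rose and 10 fell when adjusted over the list alone). The members that fell were Hsp90aa1, the inducible cytosolic Hsp90 (-0.33 ± 0.06, adjusted p = 0.0231), and Dnaja1, of the Hsp40 family (-0.30 ± 0.07, adjusted p = 0.0432). This list was higher in Model than in Control, and the shared Model libraries favour an opposite change. With each comparison using another pair of Model libraries, its median in Treatment against Model was -0.228 to -0.215 where replicate 4, highest in this score, was in the pair used, and -0.103 to -0.0606 where it was not. Clock genes had a median of 0.14 (adjusted p = 0.00843, and adjusted p = 0.586 with an estimated correlation; without Model replicate 1 adjusted p = 0.0532). The clock genes Dbp (0.64 ± 0.12, adjusted p = 0.0199) and Per1 (0.39 ± 0.09, adjusted p = 0.0399) rose. Cholesterol genes had a median of 0.12 (adjusted p = 1.50e-04, and adjusted p = 0.586 with an estimated correlation). The myelin list had a median of 0.11 (adjusted p = 0.00285, and adjusted p = 0.586 with an estimated correlation). Without Model replicate 1 its adjusted p was 0.0767, and without Treatment replicate 2 it was 0.0545. Oligodendrocyte precursor genes had a median of 0.12 (adjusted p = 0.0447, and adjusted p = 0.586 with an estimated correlation), a call that ended without Model 1 (0.0895), 2 (0.103), 3 (0.0976), Treatment 1 (0.0980), 2 (0.188) or 3 (0.0881). Of them Cspg5, a proteoglycan (0.30 ± 0.06, adjusted p = 0.0301), and Olig1, a lineage transcription factor (0.30 ± 0.07, adjusted p = 0.0446), rose. Nuclear genes of oxidative phosphorylation had a median of -0.08 (adjusted p = 8.66e-05, and adjusted p = 0.586 with an estimated correlation) and ribosomal protein genes one of -0.07 (adjusted p = 6.52e-04, and adjusted p = 0.619 with an estimated correlation). The ribosomal scores were -0.26 and -0.23 in Treatment replicates 1 and 2 and 0.01 and 0.08 in replicates 3 and 4, against -0.11 to 0.09 in Model. Without replicate 1 the adjusted p of these lists was 0.192 and 0.389, and without replicate 2 that of the ribosomal list was 0.185. The ependymal list (median -0.29, adjusted p = 0.0127, and adjusted p = 0.586 with an estimated correlation) had adjusted p = 0.484 without Treatment replicate 1 and adjusted p = 0.167 without Model replicate 2. Among other named genes, Stx1a, a synaptic fusion protein (0.57 ± 0.12, adjusted p = 0.0283), and Aldh1l1, of astrocytes (0.32 ± 0.07, adjusted p = 0.0398), rose, and Lpl, a lipoprotein lipase, fell (-0.38 ± 0.09, adjusted p = 0.0400).

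Base composition moved with this comparison. The genes higher in Treatment had a median GC content of 57.0% and the lower ones 44.5%, against 49.4% over the 17359 tested genes with a value (93.3%). The slope of expression on GC was 0.10, 0.13 and 0.07 log2 units per 10 percentage points in Treatment replicates 2, 3 and 4. In the other 9 libraries it lay between -0.08 and 0.03. Of 44 lists 17 passed (11 up, 6 down), and 0 with camera's estimated correlation (5 at an unadjusted p under 0.05, smallest adjusted p = 0.242). In fry 4 passed: dentate gyrus, endothelial, pericyte and antigen presentation genes (adjusted p = 0.0205, 0.0209, 0.0205 and 0.0209). At an unadjusted p under 0.05 there were 3436 genes, and 21 of those that passed changed at least 2-fold (17 higher, 4 lower). Values of 1767 genes (9.50%) did not overlap between groups, where chance gives 2.86%. The count of 350 became 0 without Model replicate 2 and 0 without Model replicate 3 in edgeR (2607 and 2791 genes at an unadjusted p under 0.05). It became 223 without Model replicate 4, 216 without Control replicate 4, 74 and 123 without Treatment replicates 2 and 4. The count was 130 without Treatment replicates 2 and 3 together, whose library names carry numbers apart from the other 10. It was 1 with the neocortical score as a covariate, 1099 in DESeq2 (554 higher, 545 lower), 1090 without a filter, 96 with only the 8 libraries compared, and 114 and 111 with FPKM values at pseudocounts of 0.1 and 1. With GC and length trends removed it was 283 (132 higher, 151 lower), and the clock, extracellular matrix and oligodendrocyte precursor lists did not pass (adjusted p = 0.0514, 0.0514 and 0.147).

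**Figure D2:**
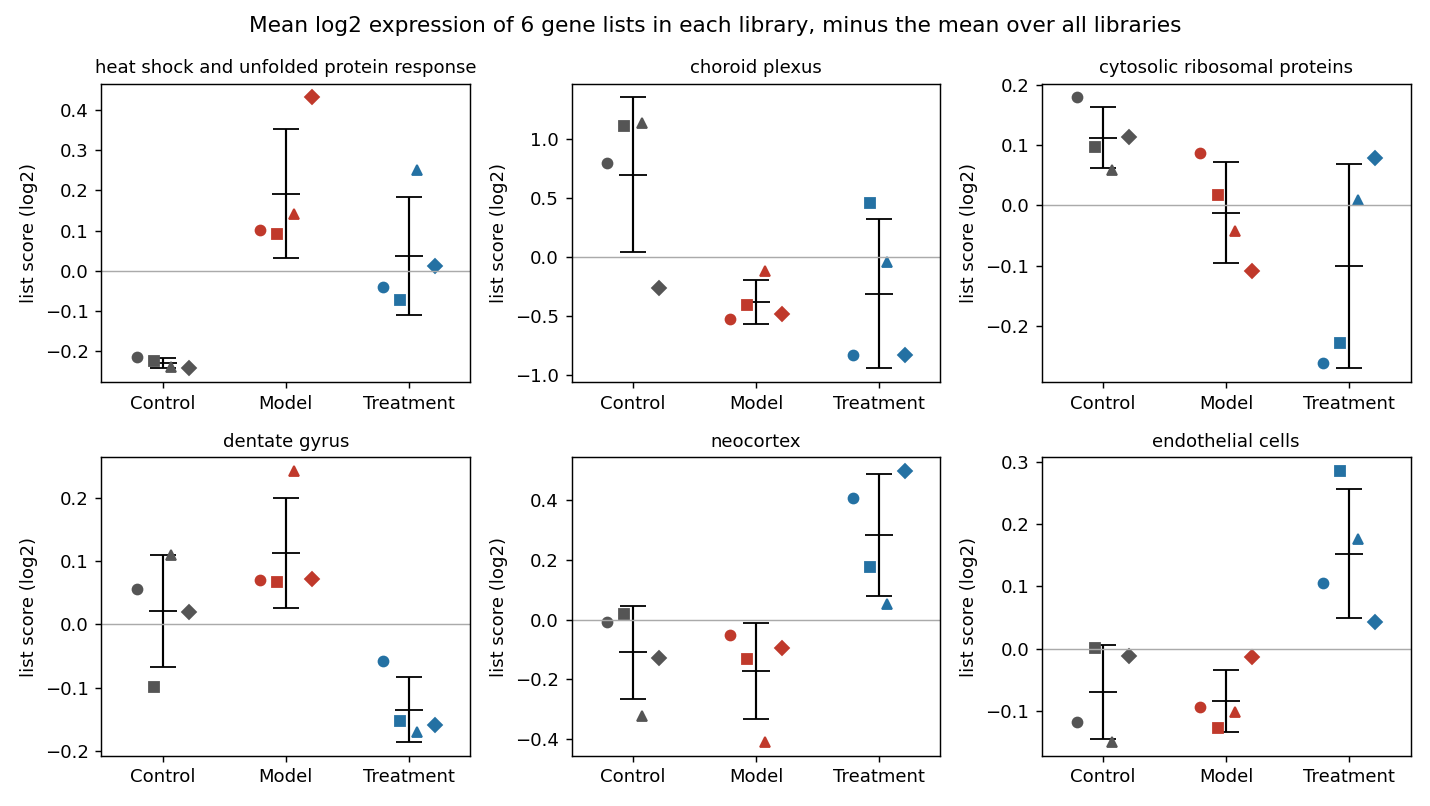
Mean log2 expression of 6 gene lists in each library minus its mean over all 12 libraries (y axis), by group (x axis), with replicates 1 to 4 as circles, squares, triangles and diamonds and the mean ± SD in black. The heat shock score is -0.21 or lower in every Control library and 0.09 or higher in every Model library, and the choroid plexus score of Control replicate 4 (-0.26) lies among those of the other groups.

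Treatment was also compared with Control, to see how stressed mice given poricoic acid A differ from unstressed ones. As lists, ribosomal protein and choroid plexus genes were lower in Treatment and heat shock and immediate early genes higher, but no list passed with a correlation between genes estimated from the data. Egr3, Fosb and Nptx2, a secreted synaptic protein, were among the genes that rose. Only 19 genes passed an adjusted p of 0.05 in edgeR, 12 higher and 7 lower.

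Egr3 went from 92.0 ± 2.84 CPM in Control to 144 ± 15.2 CPM in Treatment (0.64 ± 0.09, adjusted p = 0.0168), Fosb changed by 0.82 ± 0.13, adjusted p = 0.0272, and Nptx2 by 0.77 ± 0.14, adjusted p = 0.0499. In the list of immediate early genes 3 rose, 0 fell and 21 did not pass (7 rose and 0 fell when adjusted over the list alone). Its median was 0.17 (adjusted p = 2.64e-06, and adjusted p = 0.237 with an estimated correlation). Cbfa2t3 was higher by 0.43 ± 0.06 (adjusted p = 0.0168), Hs3st2, a heparan sulfate sulfotransferase, by 0.84 ± 0.14 (adjusted p = 0.0416), Efhd2 by 0.51 ± 0.08 (adjusted p = 0.0303) and Etv5 by 0.39 ± 0.06 (adjusted p = 0.0394). Genes of presynaptic vesicle release had a median of 0.10 (adjusted p = 2.05e-06, and adjusted p = 0.237 with an estimated correlation). Of these 0 rose over all genes and 9 adjusted over the list alone. Heat shock genes had a median of 0.22, 28 of 30 positive (adjusted p = 1.83e-11, and adjusted p = 0.286 with an estimated correlation). Of these 0 rose, 0 fell and 30 did not pass (13 rose and 0 fell when adjusted over the list alone). Hspb1, a small heat shock protein, stood at 3.18 ± 0.647 CPM in Control and 6.83 ± 1.48 CPM in Treatment (adjusted p = 0.0540).

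Of 79 ribosomal protein genes 74 were negative with a median of -0.19 (adjusted p = 6.84e-22, and adjusted p = 0.303 with an estimated correlation). Rpl39 fell, from 23.5 ± 1.61 to 12.8 ± 2.03 CPM (-0.87 ± 0.12, adjusted p = 0.0168), and 30 fell adjusted over the list alone. Nuclear oxidative phosphorylation genes had a median of -0.13 (adjusted p = 4.93e-09, and adjusted p = 0.549 with an estimated correlation). Their scores were -0.26 and -0.22 in Treatment replicates 1 and 2 and 0.06 and 0.09 in replicates 3 and 4, against 0.02 to 0.13 in Control. Tgtp1, an interferon-induced GTPase (-1.13 ± 0.19, adjusted p = 0.0394), and Slc31a1, a copper transporter (-0.63 ± 0.11, adjusted p = 0.0499), fell. So did Aspa (-0.53 ± 0.08, adjusted p = 0.0240) and Rbm3, a cold-inducible RNA-binding protein (-0.37 ± 0.07, adjusted p = 0.0499). Slc31a1 was also among the 80 genes of the split that follows choroid plexus RNA. That split sets Control replicates 1 to 3 against most Treatment libraries, so a gene lower in Treatment tends to enter it whatever its source. Choroid plexus genes had a median of -0.99 (adjusted p = 8.08e-17, and adjusted p = 0.286 with an estimated correlation). Of them 0 fell over all genes and 21 adjusted over the list alone. Ependymal genes had a median of -0.70 (adjusted p = 3.91e-08, and adjusted p = 0.286 with an estimated correlation) and red blood cell genes one of -0.39 (adjusted p = 0.00281, and adjusted p = 0.365 with an estimated correlation). The neocortical list had a median of 0.37 (adjusted p = 4.93e-09, and adjusted p = 0.237 with an estimated correlation), in which Tbr1 differed by 0.63 ± 0.12, adjusted p = 0.0584. The endothelial list had one of 0.25 (adjusted p = 4.21e-07, and adjusted p = 0.237 with an estimated correlation), in which Ly6c1 differed by 0.51 ± 0.10, adjusted p = 0.0665. The pericyte list had one of 0.20 (adjusted p = 0.00139, and adjusted p = 0.286 with an estimated correlation) and the dentate gyrus list one of -0.19 (adjusted p = 1.88e-05, and adjusted p = 0.286 with an estimated correlation). The ependymal, endothelial and neocortical scores had the smallest possible exact permutation p, 0.0286 (adjusted p = 0.133 each). Smaller differences were those of the clock list (median 0.08, adjusted p = 0.00305, and adjusted p = 0.286 with an estimated correlation) and of the list of AMPK, sirtuins and autophagy (median 0.05, adjusted p = 0.0178, and adjusted p = 0.389 with an estimated correlation). Interferon-stimulated genes had a median of 0.21 (adjusted p = 0.0122, and adjusted p = 0.549 with an estimated correlation). The AMPK list did not pass without Treatment replicate 3 (adjusted p = 0.0981) or Control replicate 4 (0.0513), nor the interferon list without Treatment replicate 3 (0.281) or Control replicate 3 (0.0520).

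Of 44 lists 15 passed (9 up, 6 down), 0 with camera's estimated correlation (5 at an unadjusted p under 0.05, smallest adjusted p = 0.237) and 0 in fry (13 at an unadjusted p under 0.05). At an unadjusted p under 0.05 there were 2581 genes, and 1346 (7.24%) did not overlap between the groups, where chance gives 2.86%. The count of 19 became 0 in edgeR without Control replicate 1 (2094 genes at an unadjusted p under 0.05), 10 and 1 without Control replicates 2 and 3. It was 9, 8 and 3 without Model replicates 1, 2 and 3, and 7, 10, 78 and 9 without Treatment replicates 1 to 4. It was 440 in DESeq2 (322 higher, 118 lower) and 19 with GC and length trends removed (14 higher, 5 lower). It was 0 in edgeR with the choroid plexus score as a covariate (1625 at an unadjusted p under 0.05) and 0 with the neocortical score (1546). It was 12 with RLE scaling, 9 in limma-voom, 748 without a filter, 2 with only the 8 libraries compared, 118 with a replicate block and 135 without Treatment replicates 2 and 3 together. FPKM values gave 14 with a pseudocount of 0.1 and 9 with 1.

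Genes that differed between Model and Control tended to differ the other way between Treatment and Model. Of the genes that passed in both Model against Control and Treatment against Model, all 43 had opposite signs and 0 had the same sign. In 30 of them expression was lower in Model and higher in Treatment (among them Myo5c, Lncppara, Dbp and mt-Nd5). In 13 it was higher in Model and lower in Treatment (among them Cbfa2t3 and Trpc6). Cbfa2t3 went from 29.3 ± 1.85 CPM in Control to 48.3 ± 1.61 in Model and 39.4 ± 1.16 in Treatment, and Myo5c from 3.94 ± 1.05 to 1.45 ± 0.112 and 3.59 ± 0.856 CPM (SD, n = 4 each). Both comparisons use the same Model libraries, which alone makes their fold changes move oppositely, so these counts do not show a reversal by themselves. Across all genes, which are not independent replicates, Pearson's r between the fold changes was -0.54. In 30 simulated data sets with no effect its mean was -0.50 (range -0.54 to -0.43). The covariance was -0.0551 against a simulated mean of -0.0333 (range -0.0372 to -0.0284). The simulated sets may lack differences shared by whole libraries, so this excess alone does not show a reversal. With the Model libraries split so that each comparison used 2 of them, the mean covariance was -0.0237 (range -0.0348 to -0.00501 over 6 splits) and r was -0.15. Over genes chosen in one part of the Model libraries and measured in the other, the median share of the change that went back in Treatment was 0.40 (range 0.26 to 0.51). In 5 of the 6 splits fewer than 20 genes passed (2 to 5), so the 200 genes of smallest p were used there, most of which did not pass.

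**Figure D3:**
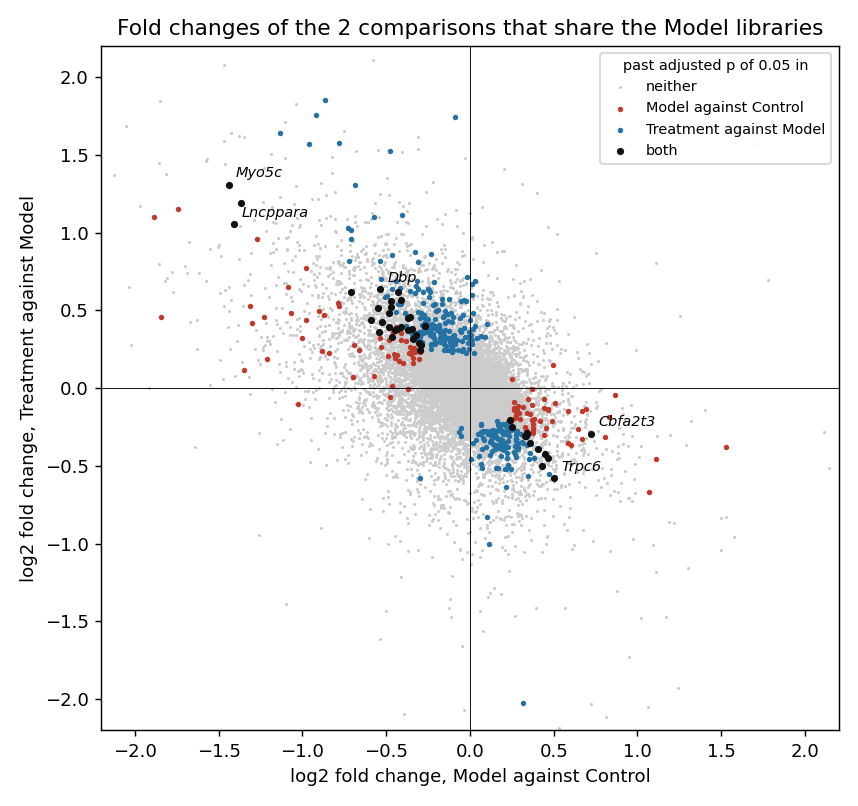
Log2 fold change of each tested gene in Model against Control (x axis) and in Treatment against Model (y axis), with genes past an adjusted p of 0.05 in one or both comparisons in colour or black. The 43 genes past in both have opposite signs; 35 genes, 1 of them past in both, lie outside the axes at 2.2, and a negative slope arises from the shared Model libraries alone.

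Genes fixed for their place in stress and depression research gave few changes. In Model against Control and Treatment against Model, Bdnf, the brain-derived neurotrophic factor, differed by 0.00 ± 0.12 (adjusted p = 0.997) and -0.16 ± 0.12 (adjusted p = 0.539), and Nr3c1, the glucocorticoid receptor, by 0.10 ± 0.07 (adjusted p = 0.556) and -0.02 ± 0.07 (adjusted p = 0.942). Fkbp5, a glucocorticoid-induced regulator of that receptor, differed by 0.23 ± 0.08 (adjusted p = 0.199) and -0.34 ± 0.08 (adjusted p = 0.0530), and Nr3c2, the mineralocorticoid receptor, by 0.06 ± 0.09 (adjusted p = 0.820) and -0.29 ± 0.09 (adjusted p = 0.108). Gfap of astrocytes differed by -0.11 ± 0.09 (adjusted p = 0.595) and -0.04 ± 0.09 (adjusted p = 0.854), and Dcx of newborn neurons by -0.21 ± 0.11 (adjusted p = 0.355) and 0.12 ± 0.11 (adjusted p = 0.621). The microglial genes Aif1 and Cx3cr1 differed by -0.66 ± 0.20 (adjusted p = 0.127) and 0.37 ± 0.20 (adjusted p = 0.348) and by -0.02 ± 0.08 (adjusted p = 0.925) and 0.06 ± 0.08 (adjusted p = 0.758). Against Control, Treatment differed in Fkbp5 by -0.11 ± 0.08, adjusted p = 0.616 and in Bdnf by -0.15 ± 0.12, adjusted p = 0.623. The cytokine genes Il1b, Il6 and Tnf were below the filter, with 53, 6 and 9 counts over all 12 libraries, so a difference in them was not detectable at this depth. Of the 44 lists, 12 passed in none of the 3 comparisons (smallest adjusted p = 0.0663). They were those of inflammatory cytokines and NF-kB, T helper 17 and regulatory T cells, lymphocytes, neutrophils and monocytes, glucocorticoid-responsive genes, corticosteroid receptors and stress neuropeptides, astrocytes, adult neurogenesis, oxidative stress and Nrf2 targets, tryptophan and kynurenine metabolism, Wnt targets, and striatum. In every list that passed, the median, the mean and the test had the same sign; among lists that did not pass, they differed in 4, 3 and 7 lists of Model against Control, Treatment against Model and Treatment against Control.

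Positions are those of the deposited table, on the GRCm39 build per the labels. Hspa5 (ENSMUSG00000026864, chromosome 2, 34661982 to 34667559), Fosb (ENSMUSG00000003545, chromosome 7, 19036621 to 19043976) and Cbfa2t3 (ENSMUSG00000006362, chromosome 8, 123351880 to 123425848) are protein-coding, as are Myo5c (ENSMUSG00000033590, chromosome 9, 75139302 to 75212733), Prox1 (ENSMUSG00000010175, chromosome 1, 189850232 to 189902911) and Pecam1 (ENSMUSG00000020717, chromosome 11, 106545043 to 106606091), whereas Lncppara (ENSMUSG00000116305, chromosome 15, 85529881 to 85552753) is a long noncoding RNA. Reads cannot always be told apart between Hspa1b and Hspa1a, Hbb-bt and Hbb-bs, Tgtp1 and Tgtp2, or the class I H2 genes, nor between Rpl39 and its pseudogenes, so values of these genes can include reads of their relatives.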

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

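The test of Cirbp and Rbm3, the test of genes that follow the neocortical score, the GC offsets and the neocortical covariate were chosen only after the results they bear on were seen. In some groups of 4 libraries 1 library lies far from the other 3: its gap to the nearest, divided by the group's whole range, is above Dixon's 95% critical value. Chance flags about 1 in 20 groups. Here 24 of 327 groups of named genes were singled out (16.35 by chance), 7 of 132 groups of list scores (6.6 by chance) and 1 of 15 of library measures (0.75 by chance).

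Model replicate 4 was high, compared with the other 3 Model libraries, in the heat shock and unfolded protein response score (0.43 against 0.0929 to 0.14) and in its members Creld2 (15.96 CPM against 12.5 to 12.99), Hsp90b1 (441 CPM against 375 to 386) and Hsph1 (415 CPM against 339 to 346). It was also high in Mbp (3578 CPM against 3092 to 3169), Olig1 (134 CPM against 113 to 117), Etv5 (86.97 CPM against 77.2 to 78.5) and the score of AMPK, sirtuins and autophagy (0.0656 against -0.0317 to -0.0196). Model replicate 1 was low in Sostdc1 (4.58 CPM against 6.39 to 6.72) and high in Hbb-bt (10.9 CPM against 7.64 to 8.10). Model replicate 2 was low in Per1 (54.98 CPM against 57.6 to 57.8) and high in the thalamus and habenula score (0.39 against -0.42 to -0.37), and Model replicate 3 was high in the dentate gyrus score (0.24 against 0.0672 to 0.0726). Among Control libraries, replicate 3 was high in Derl3 (0.931 CPM against 0.534 to 0.579), Creld2 (9.84 CPM against 7.96 to 8.22), Opalin (38.8 CPM against 32.2 to 32.9), Trpc6 (20.5 CPM against 16.1 to 16.5) and Siglech (16.1 CPM against 13.7 to 13.9) and low in Col24a1 (1.40 CPM against 2.53 to 2.77). Control replicate 1 was low in Fosb (4.18 CPM against 5.68 to 5.90) and replicate 4 in Coch (4.86 CPM against 7.85 to 8.45). Control replicate 2 was low in Inhba (5.90 CPM against 7.19 to 7.44) and high in the scores of T helper 17 and regulatory T cells (0.12 against -0.10 to -0.0838) and of lymphocytes (0.14 against -0.0868 to -0.0567). Among Treatment libraries, replicate 3 was high in Sdf2l1 (12.3 CPM against 8.57 to 8.97), Gfap (409 CPM against 315 to 326) and Htr1a (38.3 CPM against 35.02 to 35.4) and low in Lss (31.9 CPM against 37.9 to 38.97). Treatment replicate 1 was high in Cx3cr1 (53.4 CPM against 45.2 to 46.3) and in the dentate gyrus score (-0.0584 against -0.17 to -0.15), and replicate 2 in Whrn (61.4 CPM against 47.8 to 48.1). The estimated counts of Treatment replicate 4 added up to 23665426 against 19535385 to 19838009.

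Other splits of 8 libraries into 4 and 4 tested whether chance can give as many genes. Fits of all 12 libraries kept the other group as labelled. For Model against Control (147 genes) at most 1 gene passed in another split, so 1 of 35 splits, the real one, was as large. For Treatment against Model (350 genes) at most 1 gene passed in another split, again 1 of 35. The smallest possible p of such a test is 0.0286, and other splits mix labelled groups, which can widen their spread. Chance is thus less likely for these 2 comparisons, but not excluded. Nor is it excluded for Treatment against Control, where the real split gave 19 genes, the highest other 80, and 2 of 35 splits were as large. That other split set Control replicates 1, 2 and 3 with Treatment replicate 2 against the rest. All 80 genes were higher there, 20 of them among the 23 choroid plexus genes (Fisher p = 6.21e-46). The libraries are thus structured by choroid plexus RNA, across groups. The Fisher p takes genes as independent, although the choroid plexus list had an estimated correlation of 0.85, and the split was singled out for its size. It therefore overstates the evidence.

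Heat shock and unfolded protein response genes were higher in Model in 30 of 30 members (median 0.37). Choroid plexus carried over in Control dissections was tested with its score as a covariate: the median became 0.39, 1.076 of its former value, which argues against it, while genes past the threshold went from 14 to 0 (21 at an unadjusted p under 0.05 in edgeR) because the median SE went from 0.0929 to 0.132. Removing GC and length trends left 1.01 of the median and 20 genes past it. Warmer animals at sampling stay open as an explanation. The cold-inducible genes Cirbp (-0.45 ± 0.08, adjusted p = 0.0212) and Rbm3 (-0.37 ± 0.07, adjusted p = 0.0212) were lower in Model, with a mean of -0.41 (SE 0.0527). The test of these genes was chosen after related values were seen, so its outcome does not count as evidence for warmth. The heat shock list was lower in Treatment than in Model. There Rbm3 differed by -0.005 ± 0.067 (adjusted p = 0.982) and Cirbp by 0.22 ± 0.08 (adjusted p = 0.165). Within Model, replicate 4 had the highest heat shock score and 72.1 CPM of Rbm3, against 59.2, 69.3 and 71.0 CPM in replicates 1 to 3. These values do not decide on warmth. An effect of stress itself, which the design names, stays open and was not told from warmth.

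The opposite changes in Treatment of genes changed in Model may come from the Model libraries that both comparisons share. Splitting these libraries, so that none is shared, gave a negative covariance in 6 of 6 splits (mean -0.0237). By its size alone, against -0.0551 with shared libraries, the split covariance fell between the 2 bounds set beforehand. By the rule set beforehand the sign then decided, against sharing as the whole cause. However, the 6 splits reuse the same Control and Treatment libraries, so a likeness of these 2 groups can give all 6 the same sign. The split covariance was not set against simulated sets, so its sign does not settle whether sharing is the whole cause. Removing GC and length trends left 0.968 of the split covariance, which argues against that bias. A feature common to all 4 Model libraries, whether an effect of stress that the compound opposes or their handling, stays open and was not tested. The tissue make-up of the Control and Treatment libraries stays open too and was not tested on the split covariance.

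Neocortical and vascular markers were higher and dentate gyrus markers lower in Treatment than in Model. More neocortex in the Treatment dissections may account for the neocortical part. The 100 genes outside the list that rise most with its score within Control and within Model, group means removed, had a median of 0.237 in Treatment against Model (0.138 to 0.237 with any of those 8 libraries left out of choosing them), where all genes of at least 1 CPM outside the list had a median of -0.000434. A trend shared by these genes for another reason is not excluded. Of the 20 measured members of the list 18 reach 1 CPM in every group and 3 are in another list; the most abundant, Mef2c, Bcl11b and Etv1, were at 165, 163 and 259 CPM, 128, 168 and 132 CPM and 113, 141 and 132 CPM in Control, Model and Treatment, so of these 3 Mef2c alone was higher in Treatment than in both other groups. For the vascular part the neocortical covariate left 1.07 of the median (0.28 to 0.30), which argues against it there; genes past the threshold went from 3 to 0 in edgeR (15 at an unadjusted p under 0.05) as the median SE went from 0.109 to 0.170. The dentate gyrus median moved from -0.27 to -0.13 (0.493 of it), so for that part dissection and an effect of the compound both stay open; with GC and length trends removed the vascular, dentate gyrus and neocortical medians were 0.839, 0.881 and 0.926 of their values, and members past the threshold went from 3 to 5, from 5 to 6 and from 4 to 1. In the neocortical list the median went from 0.490 to 0.454 and its median SE from 0.137 to 0.143; Cux2, Lamp5 and Whrn then had adjusted p = 0.0505, 0.0626 and 0.0810, and the change of Whrn went from 0.545 to 0.367.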

How the results depend on the processing

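The GC and length offsets and the neocortical covariate were chosen after seeing the data. Counts of genes past the threshold are given for Model against Control, Treatment against Model and Treatment against Control in this order. They were 147, 350 and 19 as reported, 155, 355 and 12 with RLE scaling, 692, 1099 and 440 in DESeq2, 88, 318 and 9 in limma-voom, 783, 1090 and 748 without a filter and 192, 455 and 28 with a stricter one. Fits of only the 8 libraries compared, which estimate the spread without the other group, gave 438, 96 and 2. The fit of all 12 libraries shares 1 estimate of the spread over the groups, although the groups differ in it. The difference between 2 libraries of a group, as chi-square over degrees of freedom, reached 21.4 in Treatment, 10.9 in Model and 8.11 in Control. With the replicate number as a replicate block the counts were 228, 431 and 118. The numbers do not appear to pair the libraries: correlations of libraries of the same number, after removal of group means, lay between -0.04 and 0.11, and the own number gave the highest in 4 of 12 cases. Without Treatment replicates 2 and 3 together counts were 306, 130 and 135. FPKM values gave 5, 114 and 14 with a pseudocount of 0.1 and 5, 111 and 9 with 1. A change of at least 2-fold with an adjusted p under 0.05 left 21, 21 and 1, and the same change with an unadjusted p under 0.05 gave 174, 140 and 149. The choroid plexus covariate gave 2, 355 and 0 (for the 0, 1625 genes at an unadjusted p under 0.05 in edgeR), the neocortical covariate 163, 1 and 0 (1546 for the 0), and GC and length offsets 472, 283 and 19. Leaving out 1 library gave 8 (without Control replicate 1) to 275 (without Treatment replicate 3), 0 (without Model replicates 2 or 3; 2607 and 2791 at an unadjusted p under 0.05) to 483 (without Treatment replicate 3) and 0 (without Control replicate 1; 2094) to 78 (without Treatment replicate 3). Other libraries whose absence moved a count over 1.5 times were, in Model against Control, Control 2 (12), Model 2, 3 and 4 (14, 13 and 12) and Treatment 1 (274). In Treatment against Model they were Control 4 (216), Model 4 (223) and Treatment 2 and 4 (74 and 123). In Treatment against Control they were Control 2 and 3 (10 and 1), Model 1, 2 and 3 (9, 8 and 3) and Treatment 1, 2 and 4 (7, 10 and 9). Where the setting itself does not show it, the cause was not tested. At this depth 47.8% and 41.8% of simulated changes of 0.4 log2 units were called in the first 2 comparisons, so changes of that size can be missed.

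Lists past the threshold numbered 25, 17 and 15 as reported, 0, 0 and 0 with an estimated correlation, 2, 4 and 0 in fry, 24, 18 and 15 with a replicate block, 22, 16 and 19 with GC and length offsets, and 19 to 25, 15 to 18 and 15 to 19 leaving out 1 library. The thalamus and habenula list of Model against Control ranged from adjusted p = 3.57e-04 to 0.792 over single libraries left out and turned direction without Control replicate 1. The block ended the call of the pericyte list in Model against Control (adjusted p = 0.0556). Lists at the smallest exact p numbered 0, 4 and 3 with means and 0, 2 and 3 with medians.

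Of named genes that passed, 36, 48 and 17 in number, 586, 740 and 210 of 899, 1196 and 425 values over 25 settings stayed past in the same direction and 313, 455 and 215 were no longer past. A sign changed in 0, 1 and 0, namely for Cux2 in Treatment against Model with the neocortical covariate (-0.0277), a list to which it belongs. For fold changes in Model against Control and Treatment against Model, r was -0.54 and the covariance -0.0551. They were -0.15 and -0.0237 with the Model libraries split, where each group has fewer libraries and none is shared, -0.57 and -0.0178 for genes of at least 5 CPM, -0.49 and -0.0611 with the choroid plexus covariate, and -0.65 to -0.47 and -0.0844 (without Model replicate 1) to -0.0520 leaving out 1 library. Shared Model libraries make both negative without any effect (simulated means -0.50 and -0.0333), so a negative sign bears on the reversal only with the libraries split. The shared covariance of -0.0551 lay outside the simulated range (-0.0372 to -0.0284), and r only just outside its range (-0.539 to -0.428). The simulated sets may lack differences shared by whole libraries, such as those of choroid plexus RNA. Lying outside their range therefore does not show a reversal by itself.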

Other observations

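All genes named in this part except Cbln3, Lcn2 and Rbm3 were chosen after their values were seen. Single genes among the 43 that passed in both Model against Control and Treatment against Model are given here; no list or enrichment test joins them. They include Rsrp1, an arginine- and serine-rich protein (-0.54, adjusted p = 5.39e-04, then 0.36, adjusted p = 0.0148), Snrnp70, a component of the U1 small nuclear ribonucleoprotein (-0.30, adjusted p = 0.0438, then 0.29, adjusted p = 0.0337), and Leng8, of mRNA export (-0.36, adjusted p = 0.0468, then 0.46, adjusted p = 0.0174). These fell in Model and rose in Treatment. Upf2, a factor of nonsense-mediated decay, went the other way (0.33, adjusted p = 0.0471, then -0.31, adjusted p = 0.0402). Rsrp1 averaged 330, 227 and 291 CPM in Control, Model and Treatment, Snrnp70 406, 329 and 403 CPM and Leng8 418, 326 and 449 CPM. Nrbp2, a pseudokinase, averaged 164, 127 and 165 CPM (-0.37, adjusted p = 0.00794, then 0.37, adjusted p = 0.0130). Other genes that rose in Model and fell in Treatment were Nptx1, a neuronal pentraxin (0.34, adjusted p = 0.0277, then -0.30, adjusted p = 0.0330), Emx2, a transcription factor of hippocampal development (0.36, adjusted p = 0.0454, then -0.35, adjusted p = 0.0333), and Slc5a3, a transporter of the osmolyte inositol (0.45, adjusted p = 0.0454, then -0.42, adjusted p = 0.0376).

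Lcn2, a secreted iron-carrier protein of reactive astrocytes, averaged 0.0435, 1.14 and 1.23 CPM in Control, Model and Treatment and did not pass in Model against Control (adjusted p = 0.0802 in edgeR), with no fold given since Control is near 0 counts. Lcn2 lifts the mean change of the reactive astrocyte list to 0.35, above its median of 0.13. Genes of cerebellar neurons differed between single Model libraries and Treatment: Cbln3 was highest in Model replicate 1 (27.3 CPM) and 6.41 CPM in Control replicate 1, Gabra6, a GABA receptor subunit of cerebellar granule cells, averaged 0.686, 3.77 and 0.0468 CPM in the same order of groups, and Ppp1r17, of Purkinje cells, 0.730, 1.89 and 0.123 CPM. Gabra6 and Ppp1r17 were lower in Treatment than in Model (adjusted p = 0.0301 and 0.0337), where they were near 0 counts. No list of cerebellar genes was written beforehand, so no test of their source was made. Cirbp, which fell in Model, averaged 52.7, 38.6 and 44.8 CPM; its change in Treatment against Model did not pass (0.22 ± 0.08, adjusted p = 0.165), and Rbm3 differed there by 0.00 ± 0.07, adjusted p = 0.982.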
